A study of Mus musculus with 51 samples.

How the data were processed

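RNA from sorted thymocytes of 51 libraries was measured, 3 mice in each of 17 groups, on 2 flow cells. Viable Thy1.2-positive cells were sorted as DN, DP or CD4-negative CD8-positive cells, RNA came from snap-frozen pellets, and libraries were made with the NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument, per the labels. The deposited files give raw counts of uniquely placed reads for 54232 genes per library. The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.35, STAR 2.7 and DESeq2 with the builds GRCm38 and mm10, in no stated order. The strand setting and the annotation release behind the counts are not given in the sources used here, and without strand, reads of overlapping genes on opposite strands cannot be told apart. A set of 38 tables holds the authors' own comparisons: in them the authors deposited log2 fold changes with their standard errors, p-values with adjusted p-values, and a baseMean score, the mean normalized count over the libraries compared. Those tables list 15845 genes in all, none with a mean normalized count under 20. They were used to count the authors' calls and to take gene symbols, 179 of which differ from the reference names.

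Groups came from the genotype, stage and condition labels, and replicates from the replicate labels. Group names in the text stand for wild type, Stat5a S710F, STAT5B N642H, either of these with the label Rag2-/-, and 2 cohorts with that label alone. Titles of the libraries of mouse 104 name the Stat5a change while their genotype and condition labels name STAT5B N642H; the genotype label was followed. The title of its DN library also names a CD8-positive stage, and 2 DN libraries, STAT5B-mutant replicate 65 and second-cohort replicate 95, have names with a pair of mouse numbers, so the labels leave open whether those pools held cells of more than 1 mouse. The flow cell was read from the file names: 30 libraries were on the first and 21 on the second. All wild-type libraries were on the first, so STAT5B-mutant and wild-type cells were compared across flow cells, while the Rag2-labelled mutants were compared with controls on their own flow cell. On the first flow cell, lane 3 held the wild-type, Rag2-null control and Stat5a-mutant DN libraries, and lane 4 the Rag2-null Stat5a-mutant libraries and the DP and CD8 libraries of Stat5a mutants. Lane and group therefore coincide for Stat5a-mutant against wild-type DP and CD8 cells, Stat5a S710F in Rag2-null DN cells, and DP against DN cells of Stat5a mutants, and no fit can part them. The first and second cohorts labelled Rag2-/- were compared to show how far the flow cells differ in DN cells.

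Library totals ran from 7280107 to 57336413 counts. The median was 19277100, and totals on the second flow cell ran from 8037942 to 32817796, within the range of the first. One library stood apart in its content: in STAT5B-mutant DN replicate 93, labelled Rag2-/-, 27.73% of counts were mitochondrial and 28.59% fell in the 10 largest genes, against at most 2.94% and 7.52% in the others.

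Tests were run in R 4.3.3 with edgeR 4.0.16 on all 51 libraries: filterByExpr with a minimum count of 10 kept 18206 genes, TMM factors scaled the libraries, and glmQLFit with glmQLFTest tested each contrast of a model with 1 coefficient per group (34 residual degrees of freedom). The common biological coefficient of variation was 46%. Benjamini-Hochberg adjustment was applied per comparison, and a gene was called at an adjusted p of 0.05. The 29 comparisons were 24 of 2 groups and 5 differences of differences. Levels per library are CPM with TMM-scaled totals, with 0.5 added before any log. Fits were tested on negative binomial counts simulated around the second group's mean, with 200 genes changed. For Stat5a-mutant against wild-type CD8 cells, all libraries recovered 35% of 2-fold and 73% of 4-fold changes with 2.7% of calls false. The groups alone gave 4%, 54% and 4.9%. For STAT5B-mutant DN cells labelled Rag2-/- against controls, all libraries gave 20%, 71% and 3.2%, and the groups alone 1%, 32% and 5.7%. With 3 mice per group, 2-fold changes were often missed. False calls where groups differ in spread were not tested.

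Before the data were examined, 21 gene lists with 328 members were fixed; 312 members were tested and 16 were not. The lists covered STAT5 targets, receptor complex and TCR-induced genes, progenitor, Notch, double-positive, mature CD8 and natural killer genes, cell cycle, glycolysis, cytokine receptors, interferon response, T-ALL, apoptosis and polycomb genes, and markers of B cells, myeloid cells, erythroid cells, stroma, stress and mitochondria. They were tested in 19 comparisons with camera of limma 3.58.1, once with its preset correlation of 0.01 and once with a correlation estimated from the data, and with fry. Named genes followed a rule fixed at the same time. Stat5a, Stat5b, Rag1, Rag2, Cd4, Cd8a, Cd8b1 and the summed V segments could be named in any group. From each list up to 4 called members with the largest change were eligible, and up to 5 genes per direction with a mean log2 CPM of at least 3 whose libraries did not overlap between the groups, receptor segments and unnamed transcripts aside. For lists that did not move, 2 to 4 members are named. A few genes that the rule would allow are not reported here; they stayed in every fit, list test and count of calls, and were left out only of the named genes and of the tally of fold changes under the alternatives. Genes outside the rule are marked as chosen after their values were seen. The V segment sum covers 170 genes, 88 of them past the filter. Gene locations come from GENCODE release M21 on GRCm38, which places 18197 of the tested genes.

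Stages of 1 genotype came from the same mice where the replicate labels match, so the mouse was tried as a block. After removal of group means, 25 such pairs of libraries correlated between -0.19 and 0.85 (median 0.4), and 21 correlated best with the other library of their own mouse. Replicate numbers shared between genotypes did not pair libraries: 6 such pairs had a median correlation of -0.165. Alternatives fixed at the start were DESeq2 1.42.0, RLE factors, no filter on low counts (33601 genes), only the compared groups in the fit, each library left out in turn, the replicate block, and, for STAT5B-mutant against wild-type cells, subtraction of the difference between the cohorts labelled Rag2-/-. A fit without STAT5B-mutant DN replicate 93, labelled Rag2-/-, and STAT5B-mutant DN replicate 65 was added after seeing the data, and so was a fit of the differences between steps with the mouse as a block within each genotype. For each comparison of 3 with 3 libraries all 10 splits were tested, and 100 drawn splits for the difference between the mutations in DN cells. For the mutations in CD8 cells, which share wild-type libraries, the correlation and covariance of fold changes were set against 10 simulations without a difference; these called 0 genes in either list with edgeR and so say nothing about overlaps of calls. Chromosome shifts are medians over genes with a mean log2 CPM of at least 4 of each library's log2 difference from the wild-type mean of the same stage, centred on the library's own median. Tables were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Variants, splicing and reads per exon were not analysed here.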

Results

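Thymocytes of C57BL/6 mice were sequenced after viable Thy1.2-positive cells had been sorted by CD4 and CD8 into double-negative (DN), double-positive (DP) and CD4-negative CD8-positive cells (called CD8 cells from here on). A change in the mix of cells within such a gate cannot be told from a change within cells. The 51 libraries fell into 17 groups of 3 mice. Wild-type mice, mice with Stat5a S710F and mice with STAT5B N642H were sampled in all 3 stages, and so were both mutations on a background labelled Rag2-/-. A pair of cohorts with that label and no mutation, 1 for each mutation, gave DN cells. STAT5A and STAT5B are transcription factors that Janus kinases activate below cytokine receptors, and RAG2 is part of the enzyme that joins the gene segments of antigen receptors. The median total was 19277100 counts. Fold changes below are log2 values ± SE from edgeR, tested over 18206 genes with all 51 libraries in the fit, and levels are CPM (counts-per-million) as mean ± SD with n = 3 per group. The wild-type, Stat5a-mutant and first-cohort libraries (30) were on 1 flow cell and the STAT5B-mutant and second-cohort libraries (21) on another, so every comparison of STAT5B-mutant with wild-type cells is confounded with the flow cell. On the first, lanes follow groups, so Stat5a-mutant against wild-type DP and CD8 cells, Rag2-null Stat5a-mutant DN cells against their controls and DP against DN cells of Stat5a mutants are confounded with the lane.

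Targeted genes were read first, to see whether libraries matched their labels. Rag2 (ENSMUSG00000032864; GRCm38 chromosome 2, 101624718 to 101632529) stood at 47.7 ± 11.7 CPM in wild-type DN cells and at 1.48 ± 0.805 CPM in the first Rag2-null cohort, a log2 fold change of -5.05 ± 0.87 (edgeR adjusted p = 0.000661). In the second cohort, the DN libraries labelled Rag2-/- held 77.4 ± 5.89 CPM of Rag2, which goes against the label and lay 5.75 ± 0.9 log2 units above the first cohort (edgeR adjusted p = 0.00315). Rag2 was 0.829, 0.688 and 0.568 CPM on average in DN, DP and CD8 cells of Rag2-null Stat5a-mutant mice, and 55 ± 43.7, 47 ± 31.3 and 37.1 ± 14.5 CPM in the STAT5B-mutant libraries labelled Rag2-/-. Reads from receptor V segments, which become abundant once a receptor gene has been joined, were low in both cohorts: all V segments together gave 380 ± 56.5 CPM in wild-type DN cells, 131 ± 41.3 in the first cohort and 154 ± 8.69 in the second. In DP cells they gave 1290 ± 34.2 CPM in the wild type, 23.2 in Rag2-null Stat5a-mutant cells and 65.7 in STAT5B-mutant cells labelled Rag2-/-. Trac, the constant gene of the T-cell receptor alpha chain, averaged 63.1 CPM in wild-type DN cells, 0.843 in the first cohort and 0.308 in the second.

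Stat5a (ENSMUSG00000004043; GRCm38 chromosome 11, 100859351 to 100885169) was 178 ± 6.63 CPM in wild-type DN cells and 445 ± 202 CPM in Stat5a-mutant DN cells, a difference of 1.32 ± 0.42 that missed the test (edgeR adjusted p = 0.208). In CD8 cells it rose from 147 ± 5.45 to 1010 ± 440 CPM (2.79 ± 0.45, edgeR adjusted p = 0.000537), and in DP cells the means were 197 ± 13.1 and 361 ± 53.9 CPM (0.87 ± 0.42, edgeR adjusted p = 1). Rag2-null Stat5a-mutant cells reached 1800 ± 753 CPM in DP and 2100 ± 1090 CPM in CD8 cells. These were 2.32 ± 0.44 and 1.05 ± 0.42 above the Rag2-intact mutant (edgeR adjusted p = 0.000274 and 0.0815). Stat5b (ENSMUSG00000020919; GRCm38 chromosome 11, 100780731 to 100850724) showed no such gain in STAT5B-mutant cells, with 247 ± 36.4, 559 ± 11.6 and 230 ± 24.9 CPM in DN, DP and CD8 cells against 253 ± 17.8, 609 ± 29.8 and 324 ± 43.2 CPM in the wild type (edgeR adjusted p = 0.981, 0.958 and 0.405).

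**Figure D1:**
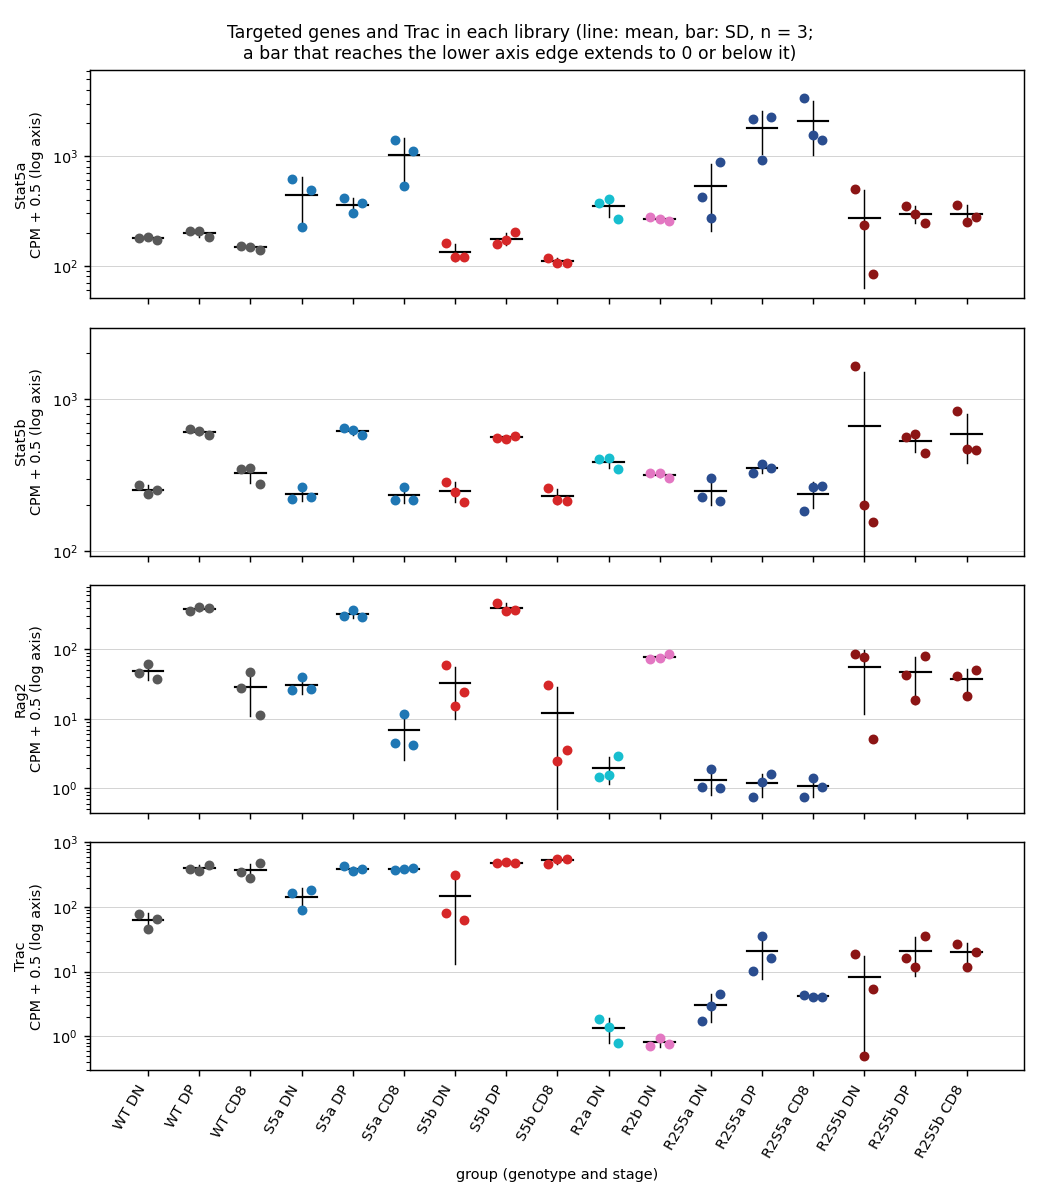
CPM of Stat5a, Stat5b, Rag2 and Trac in each of the 51 libraries, on a log axis with 0.5 CPM added; lines mark group means and bars the SD of 3 mice. Rag2 lies near 0 in the Rag2-null groups of the Stat5a cohort and not in the groups labelled Rag2-/- of the STAT5B cohort, while Trac is low in both.

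Wild-type stages were compared to set a baseline for the mutants. From DN to DP cells, edgeR called 2245 genes higher and 2721 lower. The coreceptor genes that define the gate rose: Cd4 by 7.44 ± 0.95 (2340 against 13.5 CPM; edgeR adjusted p = 4.05e-07), Cd8a by 5.59 ± 1.02 and Cd8b1 by 4.74 ± 0.97. Rag1 rose by 4.15 ± 1.06, Rag2 by 3 ± 0.77 and the amino acid transporter Slc6a19 by 6.75 ± 0.95. So did the survival gene Bcl2l1 (2.91 ± 0.24, edgeR adjusted p = 2.24e-10), the death receptor Fas (4.19 ± 0.5), and the receptor-signalling genes Themis (2.43 ± 0.54) and Rasgrp1 (1.82 ± 0.31). Genes that fell included the DN-stage marker Il2ra (-4.8 ± 0.85), Notch1 (-2.38 ± 0.57), its target Hes1 (-6.2 ± 0.93), and Il7r (-4.77 ± 1.17). With the mouse as a block and only these groups in the fit, edgeR called 4363 genes higher and 4749 lower.

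From DP to CD8 cells of wild-type mice, 1736 genes were called higher and 1247 lower. Genes that rose included the integrin Itgae (7.1 ± 1.01, edgeR adjusted p = 5e-06), the exit receptor S1pr1 (6.45 ± 1.53) and the granule gene Nkg7 (6.37 ± 0.94). Cd4 fell (-5.65 ± 0.87), Rag1 (-4.23 ± 1.06), Myb (-2.56 ± 0.74) and Bcl2l1 (-2.21 ± 0.24). With the mouse as a block and these groups alone, the counts were 3944 higher and 3797 lower; without wild-type DP replicate 2 or 5 the total of 2983 fell to 1855 or 1965.

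The effect of Stat5a S710F with Rag2 intact came first. In CD8 cells edgeR called 341 genes higher and 45 lower than in the wild type. Among them, the granzyme Gzmb rose by 7.36 ± 1.73 (287 ± 164 against 1.75 ± 0.394 CPM; edgeR adjusted p = 0.0149), the chemokine Ccl5 by 6.39 ± 1.45, interferon gamma (Ifng) by 5.54 ± 1.14, the chemokine receptors Ccr2 and Cxcr3 by 7.21 ± 1.09 and 5.87 ± 1.22, and perforin (Prf1) by 2.9 ± 0.73. Of 20 measured mature and effector CD8 T-cell genes, 7 rose and none fell (12 and 0 when adjusted over the list alone), with a median of 2.4 (limma camera adjusted p = 1.04e-10; adjusted p = 0.173 with an estimated correlation). Natural killer receptor genes such as Klre1 (6.69 ± 1.38) and Klrk1 (5.58 ± 1.05) rose, 3 of 15 measured, with a list median of 1.98 (limma camera adjusted p = 0.00047; adjusted p = 0.337 with an estimated correlation). STAT5 targets rose in 6 of 18 cases, with none lower: Socs2 by 7.01 ± 1.57, Il2ra by 3.62 ± 0.81 (97.3 against 7.91 CPM), Gzmb and Prf1. The list median was 1.33 (limma camera adjusted p = 8.32e-09; adjusted p = 0.173 with an estimated correlation).

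Lower genes in Stat5a-mutant CD8 cells included Nyap1 (-1.86 ± 0.47, edgeR adjusted p = 0.0238), Mns1 (-1.71 ± 0.45), Ptprs (-1.63 ± 0.46) and Cxxc5 (-1.51 ± 0.4). Double-positive stage genes had a median of -1.19 and mitotic and S-phase genes one of -1.15 (limma camera adjusted p = 0.000745 and 1.49e-06; adjusted p = 0.427 and 0.698 with an estimated correlation), with 1 and 0 members called. The T-cell receptor complex and its proximal signalling genes did not move: 0 of 21 were called, with Lck at -0.11 ± 0.35, Zap70 at 0.27 ± 0.29 and Cd3e at -0.15 ± 0.32, and the list median was 0.15 (limma camera adjusted p = 0.306). The total of 386 became 3422 with these groups alone and 850 with DESeq2. It was 96, 71 and 74 without wild-type replicate 1, 2 or 5, and 162 and 194 without mutant replicate 1 or 6.

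In DN and DP cells of Stat5a-mutant mice edgeR with all libraries called 0 genes. For DN cells 2145 were at an unadjusted p of 0.05, these groups alone gave 0 in edgeR, and DESeq2 called 263 higher and 12 lower. STAT5 targets had a median of 1.3, with Cish at 3.14 ± 0.97, Pim2 at 1.72 ± 0.55 and Id2 at 1.85 ± 0.57 (edgeR adjusted p = 0.193, 0.208 and 0.193); 5 of 18 rose when adjusted over the list alone (limma camera adjusted p = 1.67e-05; adjusted p = 0.459 with an estimated correlation). B-cell markers had the largest median, 3.59, with Cd79a at 3.56 ± 1.38 and Igkc at 4.05 ± 1.22, and myeloid and dendritic-cell markers one of 2 (limma camera adjusted p = 1.67e-05 and 6.27e-05; adjusted p = 0.459 for both with an estimated correlation). Mature and effector CD8 genes had a median of 1.71, cytokine receptors and Janus kinases 0.73, interferon-response genes 1.13 and mitotic genes -0.53 (limma camera adjusted p = 6.27e-05, 0.000567, 0.00148 and 0.00148; adjusted p = 0.459, 0.459, 0.459 and 0.712 with an estimated correlation). Leaving out mutant replicate 3 brought 55 edgeR calls.

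For DP cells edgeR called 0 genes, with 302 at an unadjusted p of 0.05, while these groups alone gave 36 higher and 0 lower and DESeq2 47 higher and 3 lower. Mature and effector CD8 genes were shifted as a list, with a median of 2.22 and 10 of 20 higher when adjusted over the list alone (limma camera adjusted p = 2.53e-30; adjusted p = 0.00199 with an estimated correlation). Examples were Eomes, a T-box regulator of effector cells, at 5.37 ± 1.3, Ccl5 at 4.84 ± 1.41 and Il2rb at 3.19 ± 0.91. Interferon-response genes had a median of 1.33 (limma camera adjusted p = 4.16e-19; adjusted p = 0.00512 with an estimated correlation), with Oasl2 at 2.27 ± 0.62 and Usp18 at 1.42 ± 0.45. In fry neither list passed (fry adjusted p = 0.126 and 0.165). B-cell and myeloid markers had medians of 1.77 and 1.49 in the same cells (limma camera adjusted p = 0.0036 and 4.34e-06; adjusted p = 0.469 and 0.312 with an estimated correlation). Double-positive stage genes stayed level: Rag1 -0.01 ± 0.93, Satb1 -0.04 ± 0.39, Dntt -0.19 ± 0.86, and a list median of -0.09 (limma camera adjusted p = 0.42).

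STAT5B N642H with Rag2 intact was compared with the wild type in the same way, across flow cells. CD8 cells had the most calls, 1909 genes higher and 1393 lower. Gzmb rose by 8.32 ± 1.8 (559 ± 95.2 against 1.75 ± 0.394 CPM; edgeR adjusted p = 0.00205), Ccl5 by 7.47 ± 1.52, Cxcr3 by 6.42 ± 1.25, the effector regulator Tbx21 by 5.13 ± 1.18, Prf1 by 3.23 ± 0.74 and the memory-cell adhesion receptor Cd44 by 3.31 ± 0.97. In all, 11 of 20 mature and effector CD8 genes rose and none fell, with a median of 2.65 (limma camera adjusted p = 7.17e-06; adjusted p = 0.613 with an estimated correlation). STAT5 targets followed with 7 of 18 higher, Socs2 by 6.74 ± 1.56, Il2ra by 3.42 ± 0.81 and Bcl2 by 1.93 ± 0.59 among them, and a median of 1.37 (limma camera adjusted p = 0.00019; adjusted p = 0.613 with an estimated correlation). Natural killer and gamma-delta genes rose in 6 of 15 cases (median 1.81) and interferon-response genes in 4 of 14 (median 1.14; limma camera adjusted p = 0.00355 and 0.0218; adjusted p = 0.613 and 0.698 with an estimated correlation).

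Genes that fell in STAT5B-mutant CD8 cells included the Notch target Hes1 (-5.07 ± 1, edgeR adjusted p = 0.000959), Arhgap33 (-3.66 ± 0.65), the DNA methyltransferase Dnmt3a (-1.32 ± 0.36) and Mki67, a marker of cycling cells (-2.14 ± 0.7). Mitotic and S-phase genes as a list had a median of -0.84, with 1 of 22 lower (limma camera adjusted p = 0.000485; adjusted p = 0.698 with an estimated correlation). Nr4a1, an early gene of receptor signalling, fell by 2.83 ± 0.84, yet stood at 1.84 once the difference between the cohorts labelled Rag2-/- was subtracted. B-cell markers moved in the same cells, with a median of 2.2, Igkc at 4.2 ± 1.26 and Jchain at 8.6 ± 1.57 (limma camera adjusted p = 0.0467; adjusted p = 0.698 with an estimated correlation). Receptor complex genes were not called (0 of 21; Cd3d 0.93 ± 0.5, Lat -0.34 ± 0.4, Zap70 0.15 ± 0.29; median 0.33, limma camera adjusted p = 0.299). Subtracting the cohort difference left 207 genes higher and 51 lower, so that the share of higher genes went from 57.8% to 80.2%. Without STAT5B-mutant replicate 132 the count was 1024, without wild-type replicate 1 or 2 it was 1920 or 1741, and without the filter it was 2178.

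In DP cells STAT5B N642H brought 137 genes higher and 6 lower. Genes that rose included Ccl5 by 7.37 ± 1.56, Eomes by 6.41 ± 1.32 (edgeR adjusted p = 0.0101), Ly6c2 by 6.02 ± 1.33, Cxcr3 by 5.69 ± 1.28 and Il2rb by 5.39 ± 1 (199 ± 238 against 4.79 ± 2.57 CPM). Of the 20 measured mature and effector CD8 genes 6 rose, 18 when adjusted over the list alone, with a median of 3.54 (limma camera adjusted p = 4.02e-19; adjusted p = 0.0139 with an estimated correlation). Interferon-response genes rose in 7 of 14 cases, 13 when adjusted over the list alone, with Ifi44 at 3.79 ± 0.72, Oasl2 at 3.52 ± 0.63 and Ifit1 at 3.49 ± 0.87 (median 2.61; limma camera adjusted p = 5.26e-16; adjusted p = 0.0139 with an estimated correlation). The STAT5 targets Cish (4.59 ± 1.1) and Ccnd2 (4.06 ± 1) rose, and the list had a median of 1.1 (limma camera adjusted p = 0.000578; adjusted p = 0.539 with an estimated correlation). Myeloid and B-cell markers had medians of 2.29 and 3.13 without a called member (limma camera adjusted p = 0.000133 and 0.00125; adjusted p = 0.539 and 0.55 with an estimated correlation). Double-positive stage genes were unmoved (median -0.08, limma camera adjusted p = 0.424; Cd4 -0.25 ± 0.71, Dntt -0.06 ± 0.86). The total of 143 was 402 with these groups alone, 451 with DESeq2 and 13 after the cohort difference was subtracted. It was 23, 17 and 19 without wild-type replicate 1, 2 or 5, 12 without mutant replicate 132 and 669 without mutant replicate 67.

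In DN cells STAT5B N642H gave 503 genes higher and 119 lower. B-cell markers made up the largest shift, 10 of 12 higher with a median of 6.63, Igkc by 7.74 ± 1.45 (2840 ± 4810 against 13.2 CPM; edgeR adjusted p = 0.0047) and Cd22 by 7.23 among them. A single library, mutant replicate 65, carried most of those reads, with 8390 CPM of Igkc. Myeloid and dendritic-cell markers rose in 6 of 16 cases, for example Itgax by 4.15 ± 0.99 (median 2.72). Both lists lost their call with an estimated correlation (limma camera adjusted p = 1.89e-06 and 0.000341; adjusted p = 0.598 and 0.624 with an estimated correlation). Among T-cell genes, Eomes rose by 4.24 ± 1.07, Ccr7 by 3.36 ± 0.85, Prf1 by 2.52 ± 0.72 and the natural killer receptor Ncr1 by 3.81 ± 1.06, with a median of 1.86 for mature and effector CD8 genes. Cytokine receptors and Janus kinases rose in 4 of 16 cases, Il6ra by 4.12 ± 1.01, Ifngr1 by 1.09 ± 0.27 and Jak2 by 1.03 ± 0.25 (median 1.06). Interferon-response genes rose in 2 of 14 (Usp18 1.78 ± 0.45 among them; median 1.37). For these 3 lists limma camera gave adjusted p = 0.000136, 0.000327 and 0.000456, and adjusted p = 0.598 for each with an estimated correlation. The total of 622 became 1 with these groups alone, 1497 with DESeq2, 278 without the filter and 2 after the cohort difference was subtracted. Leaving out wild-type replicate 1, 2 or 5 left 19, 10 or 23 calls, mutant replicate 132 left 284 and mutant replicate 131 left 966.

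**Figure D2:**
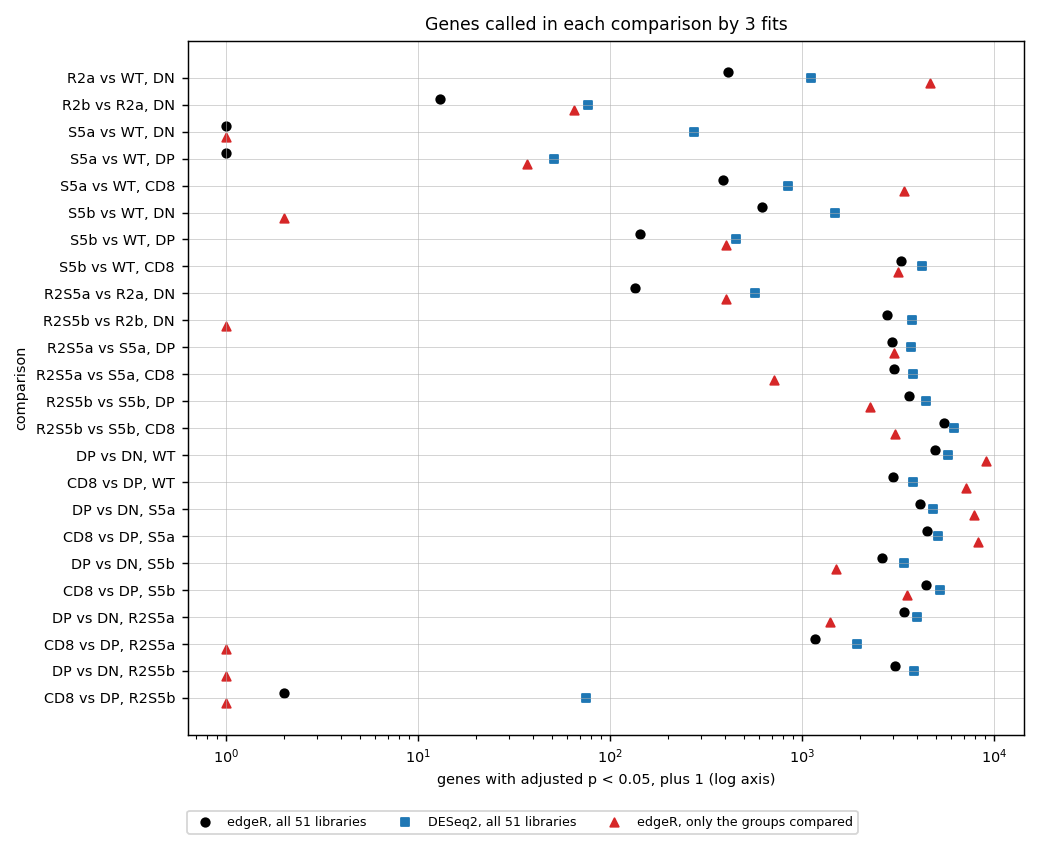
Genes called per comparison by edgeR with all 51 libraries, by DESeq2 and by edgeR with the compared groups alone, for the 24 comparisons of 2 groups. For STAT5B-mutant against wild-type DN cells the counts are 622, 1497 and 1.

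The 2 mutations were then compared in CD8 cells. Both called 260 genes higher, against 35.8 if the lists were independent, and 26 lower, against 3.4, with 0 genes called in opposite directions; log2 fold changes correlated at 0.72 across genes, with a covariance of 1.48. Shared higher genes included Ccr2 (7.21 and 7.47), S100a4, a calcium-binding protein of motile cells (7.15 and 6.97), and Il18rap, a chain of the interleukin 18 receptor (6.2 and 6.29). Shared lower genes included Ptgr1 (-2.24 and -2.24) and Pik3r2 (-1.12 and -1.62). Because the same 3 wild-type libraries served both, part of the excess may come from shared controls. How many shared calls, or how much of the correlation, those controls bring was not measured. In 10 simulations of groups without a difference the correlation was 0.07 and the covariance 0.02. Both simulated groups were drawn around the mean of the same wild-type libraries, which leaves out the error of the shared controls. Those values are therefore no baseline for the correlation of 0.72. With each comparison fitted on its own groups the shared genes numbered 1027 and 526, and with DESeq2 521 and 104. Without wild-type CD8 replicate 2 they fell to 52 and, in edgeR, 0, and the highest with 1 library left out, Stat5a-mutant CD8 replicate 3, were 273 and 40.

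Loss of Rag2 alone was then examined in DN cells. Against the wild type, the first Rag2-null cohort had 217 genes higher and 196 lower. Genes that rose included Mef2c by 5.64 ± 1.33, Ncr1 by 5.27 ± 1.13 (50.1 ± 11.9 against 1.28 ± 1.06 CPM; edgeR adjusted p = 0.00962), Itgax by 5.25 ± 1.04 and the adaptor Tyrobp by 3.91 ± 0.88. T-cell progenitor genes had a median of 1.77, Notch and pre-TCR genes 1.55, interferon-response genes 1.06 and T-ALL-associated genes 0.53, the last with Etv6 higher by 1.28 ± 0.31 (limma camera adjusted p = 0.00211, 0.0349, 0.0137 and 0.0438; adjusted p = 0.522, 0.522, 0.617 and 0.522 with an estimated correlation). TCR-induced genes had a median of -1.05, with 2 of 18 lower: Nr4a3 (-2.9 ± 0.67) and Nab2 (-2.93 ± 0.73; limma camera adjusted p = 5.51e-06; adjusted p = 0.467 with an estimated correlation). Cd8a (-3.98 ± 0.96), Cd8b1 (-4.04 ± 0.95), Rag2 and the glycolytic enzyme Ldha (-1.2 ± 0.32) fell. Double-positive stage, mitotic and glycolysis genes had medians of -0.61, -1.35 and -0.67 (limma camera adjusted p = 0.0137, 2.15e-07 and 0.00311; adjusted p = 0.522 for each with an estimated correlation). Receptor complex genes stayed level (0 of 21; Lck 0.4 ± 0.35, Cd3e 0.58 ± 0.32; median 0.3, limma camera adjusted p = 0.493). Calls numbered 4665 with these groups alone, 1110 with DESeq2 and 160 without the filter (63 higher, 97 lower). Any single library left out brought them to between 63 (wild-type replicate 2) and 184 (wild-type replicate 1).

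The second Rag2-labelled cohort differed from the first in 12 genes, 5 higher and 7 lower. Rag2 was among the higher ones. The lower ones included the early-response genes Egr1 (-5.24 ± 0.95; 3.04 ± 1.52 against 115 ± 122 CPM; edgeR adjusted p = 0.0165), Nr4a1 (-4.67 ± 0.92), Jund (-1.92 ± 0.37) and Sertad1 (-2.25 ± 0.47). Stress and dissociation genes, which cells switch on during handling, had a median of -2.7, with 9 of 12 lower when adjusted over the list alone (limma camera adjusted p = 5.47e-21; adjusted p = 0.00184 with an estimated correlation). TCR-induced genes, several of them early-response genes, had one of -1.1 (limma camera adjusted p = 1.13e-10; adjusted p = 0.0277 with an estimated correlation). In fry only the stress list passed (fry adjusted p = 0.0077 and 0.0992). Cohort and flow cell are the same split here. Without first-cohort replicate 3 or 4 edgeR called 0 genes, and without second-cohort replicate 106, 90 or 95 it called 2, 2 or 1; these groups alone gave 64 and DESeq2 76.

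The mutations were next compared with DN cells labelled Rag2-/- of their own cohort. With Stat5a S710F, 117 genes were higher and 18 lower. Of the higher genes, Cd74 rose by 5.71 ± 1.31 (1360 ± 1610 against 25.9 CPM; edgeR adjusted p = 0.0304), H2-Aa by 5.77 ± 1.4, Xcr1 by 7.9 ± 1.66 and Flt3 by 5.54 ± 1.4, and 5 of 16 myeloid and dendritic-cell markers rose in all (median 2.58; limma camera adjusted p = 4.89e-06; adjusted p = 0.249 with an estimated correlation). Thymic stroma markers rose in 3 of 11 cases (median 0.86; limma camera adjusted p = 0.0256; adjusted p = 0.261 with an estimated correlation), though with these groups alone the median was -0.26. Icos, a costimulatory receptor (2.88 ± 0.65, 82.4 ± 32.9 against 11.2 ± 2.66 CPM), Nab2 (2.95 ± 0.73), and the kinase Zap70 (1.2 ± 0.29) rose, while Snx13 (-1.15 ± 0.24), Def8 (-1.23 ± 0.26) and Atp8a1 (-1.09 ± 0.27) fell. STAT5 targets and TCR-induced genes had medians of 1.09 and 0.89, with 4 and 5 of 18 higher when adjusted over the list alone (limma camera adjusted p = 9.46e-05 and 0.000174; adjusted p = 0.249 for both with an estimated correlation). T-ALL-associated genes were not called (0 of 16; Gata3 0.51 ± 0.37, Runx1 -0.99 ± 0.36; median -0.27, limma camera adjusted p = 0.175). The total of 135 was 0 without mutant replicate 6, which held 3210 CPM of Cd74, and 4, 3 and 7 without control replicate 3, 4 or 5. It was 364 without mutant replicate 4, 401 with these groups alone, 567 with DESeq2 and 86 without the filter. The called rise of Cd8a (4.55 ± 0.98) and Cd8b1 (3.75 ± 0.94; -0.18 without it) came from replicate 6, with 329 CPM of Cd8a against 9.89 and 9.13 in replicates 3 and 4 and 6.02, 5.62 and 3.19 in the controls.

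With STAT5B N642H, in DN libraries labelled Rag2-/-, edgeR called 1986 genes higher and 806 lower, whereas these groups alone gave 0 calls (2113 at an unadjusted p of 0.05) and DESeq2 2784 higher and 945 lower. Genes that rose included Gzmb by 6.89 ± 1.66 (2060 ± 3210 against 17.4 CPM; edgeR adjusted p = 0.0064) and lymphotoxin (Lta) by 6.86 ± 1.26, as did 8 of 18 STAT5 targets, including Id2 (2.63 ± 0.58) and Tnfrsf18 (2.72 ± 0.6), with a median of 1.34. TCR-induced genes rose in 11 of 18 cases and fell in 1: Icos by 3.38 ± 0.66, the inhibitory receptor Pdcd1 by 4.06 ± 0.91 and Tnfrsf9 by 3.78 ± 1.11, with a median of 2.61. Zap70 rose by 2.42 ± 0.31 (239 ± 169 against 44.8 ± 1.39 CPM; edgeR adjusted p = 1.62e-05) and Cd8a by 5.2 ± 1.02. Cd8a stood at 180 CPM in replicate 104, whose title names a CD8-positive stage, and at 14.4 and 5.82 CPM in replicates 93 and 94; without replicate 104 its change was 2.39 ± 0.85, and with these groups alone it was not called. Cell-cycle inhibitor genes of the T-ALL list, Cdkn2a (7.73 ± 1.9) and Cdkn2b (7 ± 1.52), rose with Gata3 (1.67 ± 0.38), while Notch1 fell by 1.91 ± 0.56 (789 against 2980 CPM) and Runx1 (-1.11 ± 0.37), and the list median was -0.42 (limma camera adjusted p = 0.393). Myc (-1.24 ± 0.33), Hivep3 (-3.34 ± 0.69), Angpt1 (-3.71 ± 1.02) and Cd28 (-2.82 ± 0.84) fell. Glycolysis genes had 6 of 15 higher (Pfkp 2.53 ± 0.49, Eno1 2.19), and the median of polycomb and DNA methylation enzymes was -0.34, with Dnmt1 lower (-1.18).

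Signs of RNA quality and of other cells moved in those DN libraries too. All 7 measured mitochondrially encoded genes rose (mt-Nd4 3.71 ± 0.64; 10800 ± 16600 against 823 CPM; median 3.51), and 27.73% of the counts of mutant replicate 93 were mitochondrial, against at most 2.94% in any other library. B-cell and myeloid markers had medians of 3.98 and 2.97, and stress and dissociation genes one of 2.19. For STAT5 targets, TCR-induced, glycolysis, polycomb, mitochondrial, B-cell, myeloid and stress genes limma camera gave adjusted p = 7.82e-05, 0.000631, 0.0166, 0.0366, 2.28e-05, 0.0117, 0.0366 and 0.0085; in that order, adjusted p = 0.316, 0.316, 0.546, 0.475, 0.316, 0.56, 0.698 and 0.475 with an estimated correlation. Without control replicate 106, 90 or 95 the total of 2792 was 834, 868 or 1271. Scaling with RLE factors raised the median over all genes from 0.107 to 0.171 and gave 2356 genes higher and 707 lower.

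The lists for both mutations in DN cells labelled Rag2-/- shared 67 higher genes, against 12.8 if independent, and 13 lower genes, against 0.8, with 0 in opposite directions and a correlation of 0.57. Examples with the value for Stat5a S710F first were the creatine kinase Ckb (4.5 ± 0.97 and 5.89 ± 1.03), Icos (2.88 and 3.38), Nab2 (2.95 and 2.85), the NF-kappa-B genes Relb (2.68 and 2.63) and Nfkbia (2.08 and 1.99), and the condensin gene Smc4 (-0.85 and -1.15). With each comparison fitted on its own groups 0 genes were shared, and with DESeq2 337 and 46. In edgeR without Stat5a-mutant replicate 6 they were 0 and 0, without control replicate 3, 4 or 5 of that mutation 1, 1 or 2 higher and 1, 0 or 2 lower, and without mutant replicate 4 they were 141 and 62. A test of the difference between the mutations called 0 genes (edgeR; 1281 at an unadjusted p of 0.05), 0 with these groups alone and 56 with DESeq2. Leaving out STAT5B-mutant replicate 94, 93 or 104 brought 161, 15 or 10 calls, and Stat5a-mutant replicate 6 brought 6.

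Mutant cells labelled Rag2-/- were compared with Rag2-intact ones in DP and CD8 cells. In Stat5a-mutant DP cells 1642 genes were higher without Rag2 and 1315 lower. Genes that rose included Notch1 by 3.45 ± 0.6 (3110 against 284 CPM; edgeR adjusted p = 8.28e-05), Dtx1 by 5.41 ± 0.87, Hes1 by 4.51 ± 0.86, Il2ra by 4.14 ± 0.83, the stem-cell factor receptor Kit by 4.87 ± 0.84 and Bst1 by 8.26 ± 0.94, with 5 of 13 Notch and pre-TCR genes higher and 1 lower (median 2.87; limma camera adjusted p = 0.00317; adjusted p = 0.255 with an estimated correlation). Tcrg-C1 (5.19 ± 0.56) and Sox13 (4.23) of the gamma-delta lineage, Myc (3.08 ± 0.36, edgeR adjusted p = 9.79e-08), the DNA methyltransferase Dnmt3b (3.07 ± 0.37), the glycolytic enzyme Hk2 (2.43) and the replication gene Mcm6 (1.61) rose as well. TCR-induced genes fell in 11 of 18 cases, 13 when adjusted over the list alone: Cd5, a gauge of receptor signal strength (-5.48 ± 0.67; 7.98 ± 1.85 against 356 ± 20.5 CPM; edgeR adjusted p = 3.41e-07), Nr4a3 (-5.16 ± 0.77), Nab2 (-5.12 ± 0.81) and Egr3 (-5.59 ± 1.09; median -2.17; limma camera adjusted p = 1.8e-07; adjusted p = 0.2 with an estimated correlation). Receptor complex genes fell in 2 of 21 cases (Rasgrp1 -1.81 ± 0.31, Cd247 -1.21 ± 0.3; median -0.62) and double-positive stage genes in 4 of 16 (Satb1 -1.75 ± 0.4, Rag2 -8.91 ± 1.04; median -1.29; limma camera adjusted p = 0.00467 and 0.000653; adjusted p = 0.563 and 0.444 with an estimated correlation). Without Rag2-null replicate 6 the total of 2957 was 1539, and without Rag2-intact replicate 1 or 6 it was 1726 or 1881.

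In Stat5a-mutant CD8 cells 1683 genes were higher without Rag2 and 1337 lower, and with these groups alone 303 and 412, which took the share of higher genes from 55.7% to 42.4%. Mature and effector CD8 genes fell in 7 of 20 cases: Prf1 (-4.78 ± 0.8; 6.28 against 172 CPM; edgeR adjusted p = 9.08e-05), Cxcr3 (-3.43) and S1pr1 (-3.71; median -1.74). Interferon-response genes fell in 9 of 14 (Mx1 -5.15 ± 1.12, Ifi44 -4.95, Oasl2 -3.43 ± 0.61; median -1.93) and TCR-induced genes in 8 of 18 (Cd5 -5.11 ± 0.66, Nr4a3 -3.25 ± 0.69, Egr2 -2.89; median -1.24). For these 3 lists limma camera gave adjusted p = 3.34e-06, 1.24e-06 and 9.6e-06; adjusted p = 0.434, 0.309 and 0.309 with an estimated correlation. Higher genes included Hes1 by 5.25 ± 0.88, Kit by 4.76 ± 0.83 (edgeR adjusted p = 0.000144), Sox13 by 5.32 ± 0.8, the cytokine receptor Il9r by 5.14, the imprinted transcript H19 by 8.59 ± 1.69 and Cdkn2a by 6.71 ± 1.73. STAT5 targets did not move as a list (1 higher and 1 lower of 18; Cish 0.37 ± 0.89, Bcl2 -0.45 ± 0.58, Myc 0 ± 0.33; median 0.18, limma camera adjusted p = 0.664). The total of 3020 was 1699, 2013 or 1923 without Rag2-intact replicate 1, 3 or 6.

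STAT5B-mutant DP cells labelled Rag2-/- had 1944 genes higher and 1688 lower than Rag2-intact ones. Sox13 rose by 7.3 ± 0.86 (edgeR adjusted p = 1.58e-07), Tcrg-C1 by 5.52 ± 0.56 (1150 against 24.9 CPM), the ETS factor Erg by 5.98, Hes1 by 5.27 ± 0.9, Notch1 by 2.66 ± 0.58, Kit by 4.03 ± 0.8, Il2ra by 3.66 ± 0.81 and Dnmt3b by 3.92 ± 0.38. TCR-induced genes fell in 9 of 18 cases (Cd5 -5.95 ± 0.69, 4.61 ± 1.85 against 285 ± 36.9 CPM, edgeR adjusted p = 1.1e-07; Nr4a1 -4.59 ± 0.91; Nab2 -4.05 ± 0.76; median -1.95), and double-positive stage genes in 5 of 16 (Satb1 -2.88 ± 0.41, Cd4 -2.24 ± 0.75, Rag1 -2.9 ± 1; median -1.57). Rag2 fell by 3.08 ± 0.77, to 47 ± 31.3 CPM. For the pair of lists limma camera gave adjusted p = 1.61e-05 and 0.000557; adjusted p = 0.507 and 0.642 with an estimated correlation. STAT5 targets split: 9 rose, for example Socs3 (1.71 ± 0.47), Cish (3.24 ± 0.97) and Bcl2 (2.38 ± 0.6), and 4 fell, Bcl2l1 (-1.74 ± 0.23), Ccnd3 (-2.13 ± 0.29), Pim2 (-1.59 ± 0.55) and Prf1 (-3.17 ± 0.75), with a median of 1.88 (limma camera adjusted p = 0.15). Without Rag2-intact replicate 131 the total of 3632 was 2246, and with these groups alone 2272.

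STAT5B-mutant CD8 cells labelled Rag2-/- had 2902 genes higher and 2612 lower than Rag2-intact ones. Lower genes were 11 of 20 in the mature and effector list, with Eomes at -7.21 ± 1.22 (edgeR adjusted p = 5.09e-05), Prf1 at -5.2 ± 0.81, Ccl5 at -7.32 and S1pr1 at -5.44 (median -2.54), 8 of 14 interferon-response genes (Ifit3 -3.61, Isg15 -2.45 ± 0.59; median -1.92) and 7 of 18 TCR-induced genes (Cd5 -5.63 ± 0.68, Nab2 -3.76; median -1.6). T-ALL-associated genes rose in 6 of 16 cases and fell in none: Myb by 3.33 ± 0.77, Notch1 by 2.04 ± 0.56 and Runx1 by 1.64 (median 0.77). Hes1 rose by 7.25 ± 1.05 (42.3 against 0.268 CPM), Erg by 6.66 ± 1.34, Kit by 3.98 ± 0.8, Il2ra by 3.54 ± 0.8 and both STAT5 genes, Stat5a by 1.44 ± 0.42 and Stat5b by 1.36 ± 0.41 (edgeR adjusted p = 0.01 and 0.0114). For the mature, interferon, TCR-induced and T-ALL lists limma camera gave adjusted p = 5.37e-05, 0.00175, 0.00186 and 0.0277; adjusted p = 0.636, 0.65, 0.636 and 0.636 with an estimated correlation. Without Rag2-intact replicate 132 the total of 5514 was 3290, and with these groups alone 3069.

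**Figure D3:**
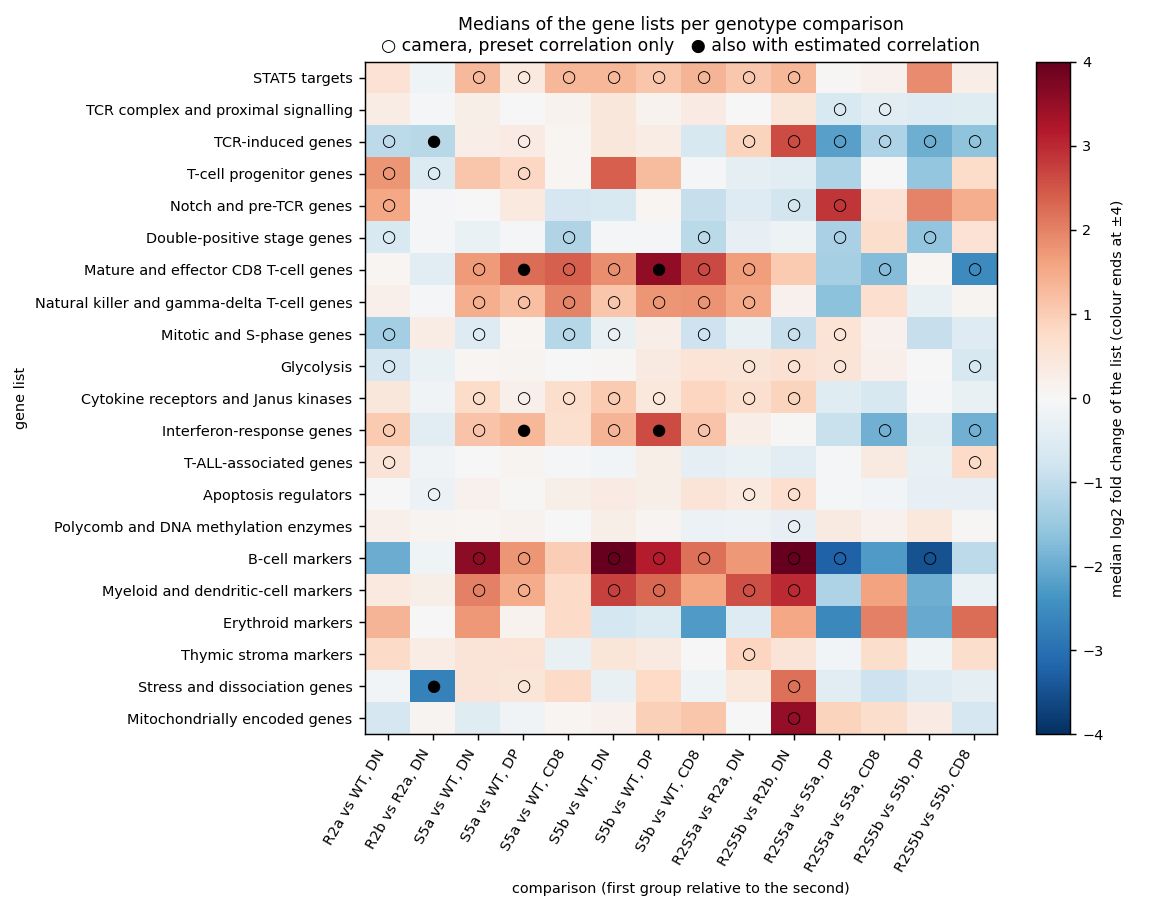
Median log2 fold change of the 21 gene lists in the 14 genotype comparisons; an open circle marks a list called by limma camera with the preset correlation and a filled one a list that also passed with an estimated correlation. Mature and effector CD8 genes are at 2.22 and 3.54 in mutant DP cells, and TCR-induced genes at -2.17 and -1.95 in DP cells labelled Rag2-/- against Rag2-intact ones. Of the 21 lists, fry called 0, 0 and 3 in DN, DP and CD8 cells of Stat5a mutants and 2, 3 and 5 in those of STAT5B mutants against wild type, 0 for the first Rag2-null cohort and 1 between the cohorts. It called 0 for Stat5a S710F and 6 for STAT5B N642H in DN cells labelled Rag2-/-, and for that label 4 and 4 in Stat5a-mutant and 6 and 5 in STAT5B-mutant DP and CD8 cells.

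Changes with the Rag2-/- label were compared between the mutations. In DP cells 859 genes were higher in both, against 175.3, and 772 lower, against 121.9, with 7 opposite and a correlation of 0.67. In CD8 cells the counts were 807 against 268.3, 630 against 191.8 and 92 opposite, with a correlation of 0.58. Libraries of both mutants had chromosome 15 raised (below), whose part in the lists was not tested. Shared genes in DP cells included Tcrg-C4 (6.09 and 6.07), the phosphatase Ptpn13 (6.67 and 6) and the signalling inhibitor Spred1 (-5.02 and -5.67). With each CD8 comparison fitted on its own groups the shared genes numbered 195 and 208. With 1 library left out the lowest were 598 and 470 in DP and 474 and 485 in CD8 cells.

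Stages within the mutants were compared last. In Stat5a-mutant mice DP cells differed from DN cells in 1544 genes higher and 2580 lower, with Cd4 at 6.85 ± 0.92, Bcl2l1 at 2.83 ± 0.24, Il2ra at -4.65 ± 0.85 and Tcrg-C1 at -5.79 ± 0.57. Of the 4966 genes called in the wild type, 3162 (63.7%) changed the same way and 0 the opposite way. STAT5B-mutant mice had 1093 higher and 1527 lower (Cd4 7.04 ± 0.93, Bcl2l1 2.65, Il2ra -3.55 ± 0.8, Sox13 -6.37), with 2072 (41.7%) shared and 97.9% of the wild-type genes changing with the same sign. That share was 15.3% with the groups alone, and 22.9% or 24.9% without DP replicate 67 or 131. CD8 cells differed from DP cells in 2644 genes higher and 1838 lower in Stat5a-mutant mice, with Eomes at 5.02 ± 1.1, Prf1 at 4.15 ± 0.78 and Gzmb at 4.7 ± 1.5, and in 2367 and 2056 in STAT5B-mutant mice, with Itgae at 4.06 ± 0.86, Klrd1 at 4.06 ± 1.02 and Tcf7, a factor of naive cells, at -1.8 ± 0.44. Of the 2983 wild-type changes in this step, 77% and 68.9% were shared, the second 39.2% with the groups alone. Stat5a-mutant totals per step were 7912 and 8229 with the groups alone and 8518 and 8823 with the mouse as a block too. For differences between mutant and wild-type steps edgeR with all libraries and no block called 0 genes each (273 and 598 at an unadjusted p of 0.05 with Stat5a S710F, 781 and 1254 with STAT5B N642H). DESeq2 called 26, 43, 27 and 42. A test added after the data were seen took the mouse as a block within each genotype and these groups alone, and edgeR called 2 and 2087 genes with Stat5a S710F and 246 and 778 with STAT5B N642H, the 246 from 2 mutant mice that had both stages.

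Stages were compared in mutants labelled Rag2-/- as well. Rag2-null Stat5a-mutant DP cells had 1082 genes higher and 2310 lower than DN cells, with Cd4 at 6.22 ± 0.9 (803 against 10.7 CPM; edgeR adjusted p = 2.12e-05), Cd8a at 3.61 ± 0.93, Bcl2l1 at 1.79 ± 0.23 and Top2a, a gene of dividing cells, at 2.17. Genes that fell included Klrk1 (-10.77 ± 1.4), Ncr1 (-9.01 ± 1.37), Xcl1 (-9.75) and Gzmb (-8.41), Itgax (-7.23) and H2-Ab1 (-6.2). Of the wild-type changes 20.9% were shared and 143 genes went the opposite way. The share was 7.9% with the groups alone, 11% with the mouse as a block, where 424 genes went the opposite way, and 13.6% without DP replicate 4. The 143 were 33 without DP replicate 6, 53 and 55 without DN replicates 3 and 4, and 229 without DN replicate 6. From DP to CD8 cells 896 genes rose and 278 fell, Tnfrsf9 by 9.71 ± 1.51, Ccl5 by 7.12, Nkg7 by 6.91 ± 0.97, Il2rb by 5.34 and Cd4 (-4.81 ± 0.84; edgeR adjusted p = 0.00152). edgeR with these groups alone called 0 genes in that step (866 at an unadjusted p of 0.05), and the count was 1932 with DESeq2, 147 without CD8 replicate 1, 187 without DP replicate 4 and 3379 without CD8 replicate 6.

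In STAT5B-mutant libraries labelled Rag2-/-, DP cells had 794 genes higher and 2273 lower than DN cells. Cd4 rose by 7.32 ± 0.96 (418 against 2.68 CPM; edgeR adjusted p = 7.4e-06), Cd8b1 by 5.98 and Cd28 by 2.94, and Il1rl1 fell (-10.06 ± 1.89), the cytokine receptor chain Il18r1 (-7.99), Ncr1 (-6.08) and Eomes (-5.49). Mitochondrial reads of DN replicate 93 moved with this step (mt-Co1 -2.8, but 0.19 without that library). edgeR with these groups alone gave 0 calls, and so did the mouse as a block (1201 and 1574 at an unadjusted p of 0.05). Without DN replicate 104 the total of 3067 was 5910, and without DP replicate 94 or 104 it was 1465 or 1721; RLE factors moved the median over all genes from -0.06 to -0.148. From DP to CD8 cells a single gene changed, Cd4 (-4.83 ± 0.84; 14.7 against 418 CPM; edgeR adjusted p = 0.0246), with 493 genes at an unadjusted p of 0.05 and 62 higher and 12 lower in DESeq2. With these groups alone or with the mouse as a block edgeR called 0 genes (151 and 1967 at an unadjusted p of 0.05), and without DP replicate 129 it called 34.

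**Figure D4:**
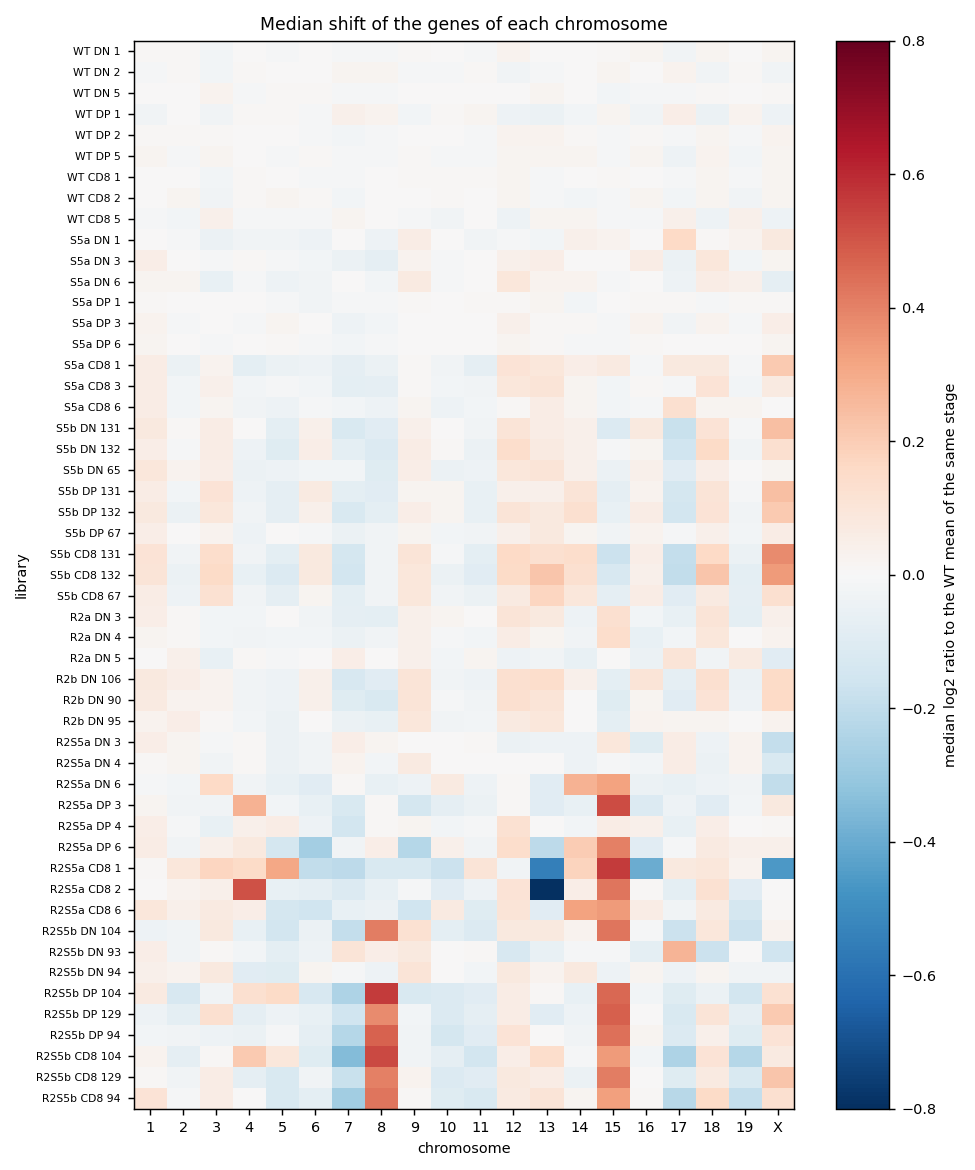
Median log2 shift of the genes of each chromosome in the 51 libraries. In the 6 DP and CD8 libraries of STAT5B-mutant mice labelled Rag2-/- the medians of chromosomes 8 and 15 were 0.33 or more.

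The submitters' own tables were counted beside these fits. In the authors' deposited table, genes with a mean normalized count of at least 20 and past their test numbered 3034, 183 and 4113 for Stat5a-mutant against wild-type DN, DP and CD8 cells, and 2176, 871 and 4366 for STAT5B-mutant cells. The first and second cohorts labelled Rag2-/- against wild-type DN cells gave 5001 and 6845 in the authors' deposited table, the mutations against their cohorts 1545 and 1116, and CD8 against DP cells of STAT5B-mutant mice labelled Rag2-/- gave 10.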

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

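Tests chosen only after the result was seen were those of the Rag2 reads, the mouse as a block in the differences between steps, and those on chromosomes 8 and 15. The others in this part were set down before their values were seen.

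List medians whose change between stages, or between mutations, differed when the difference itself was tested with limma camera are given here as log2 differences. In Stat5a-mutant compared with wild-type cells, the DP minus DN change differed for mitotic and S-phase genes by 0.59 and for B-cell markers by -1.38, and the CD8 minus DP change for STAT5 targets by 0.7, double-positive stage genes by -1.09 and mitotic genes by -1.21. In STAT5B-mutant compared with wild-type cells, the DP minus DN change differed for the receptor complex by -0.22, mature CD8 genes by 2.12, mitotic genes by 0.59, interferon-response genes by 1.39, B-cell markers by -3.46 and stress genes by 0.94. Without DN replicate 65 the B-cell value turned to 1.38 and the stress value was 2.28; mature CD8 genes were at 1 without DP replicate 132 and mitotic genes at 0.18 without DP replicate 131. The CD8 minus DP change differed there for STAT5 targets by 0.33, TCR-induced genes by -1, double-positive stage genes by -1.07, mitotic genes by -1.19 and interferon-response genes by -1.78. Between the mutations in DN cells labelled Rag2-/-, the effect of STAT5B N642H minus that of Stat5a S710F differed for natural killer genes by -1.25, mitotic genes by -0.64, stroma markers by -2.07 and mitochondrially encoded genes by 3.52. The last rests on STAT5B-mutant DN replicate 93, with 27.73% mitochondrial counts against 1.84 and 1.11% in replicates 104 and 94, and was 0.64 without it. Without Stat5a-mutant replicate 6 the first 3 were -0.41, -0.22 and -0.65. Apart from the B-cell value of STAT5B mutants, none of the 20 changed sign with 1 library left out. All 20 passed with the preset correlation and none with the estimated one, where the lowest limma camera adjusted p was 0.473, and fry called 0 lists in each. Per gene, edgeR called 0 genes in each of these 5, with 273, 598, 781, 1254 and 1281 at an unadjusted p of 0.05, and DESeq2 26, 43, 27, 42 and 56. With the groups alone edgeR called 0, 745, 2 and 4 for those between steps, and 2, 2087, 246 and 778 with the mouse as a block too.

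Each comparison of 3 with 3 libraries was set against all 10 splits of its libraries, fitted on those libraries alone with edgeR; 10 are too few splits for a share under 0.05. Against wild type, the real split called most genes, so 1 of 10 reached its count, for the first Rag2-null cohort (4665, highest other 0), Stat5a-mutant DP (36, other 1) and CD8 cells (3422, other 0), and STAT5B-mutant DN (1, other 0), DP (402, other 0) and CD8 cells (3174, other 0). In Stat5a-mutant DN cells all 10 called 0, with 2145 genes at an unadjusted p of 0.05 in all libraries and 275 called by DESeq2. The cohorts labelled Rag2-/- differed from each other in 64 genes (other 4; 1 of 10). In DN cells labelled Rag2-/-, Stat5a S710F gave 401 (other 5; 1 of 10), while STAT5B N642H gave 0 with all 10 splits at 0, 2113 genes at an unadjusted p of 0.05 and 2792 calls from all libraries. Mutant cells labelled Rag2-/- against Rag2-intact ones gave 1 of 10 each: 3034 (other 0) in DP and 715 (other 0) in CD8 cells for Stat5a, 2272 (other 1) and 3069 (other 0) for STAT5B.

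Between stages the count was likewise 1 of 10 for DP against DN cells in wild type (9147, highest other 0), Stat5a mutants (7912, other 0), STAT5B mutants (1504, other 0) and Rag2-null Stat5a mutants (1404, other 0). For CD8 against DP cells it was 1 of 10 in wild type (7136, other 0), Stat5a mutants (8229, other 0) and STAT5B mutants (3548, other 0). In STAT5B mutants labelled Rag2-/- the counts of edgeR were 0 for DP against DN (other 4; 1201 at an unadjusted p of 0.05; 3067 from all libraries) and 0 for CD8 against DP (other 0; 151; 1 from all libraries), so all 10 splits reached them. CD8 against DP in Rag2-null Stat5a mutants likewise gave 0 in edgeR (other 10; 866 at an unadjusted p of 0.05; 1174 from all libraries), reached by 10 of 10. Of the differences, CD8 minus DP called 745 for Stat5a (other 0) and 4 for STAT5B (other 0), and DP minus DN called 2 for STAT5B (other 0), each reached by 1 of 10; DP minus DN for Stat5a called 0 (other 0; 10 of 10; 273 at an unadjusted p of 0.05, edgeR). For the difference between mutations in DN cells, 100 of 100 drawn splits reached the count of 0 (edgeR; highest other 15; 1281 at an unadjusted p of 0.05). Any split reaches a count of 0, so where the real count was 0 the splits say nothing about chance.

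Rag2 was counted in the libraries labelled Rag2-/- of the second cohort, 5.75 ± 0.9 above those of the first. Cells with a working Rag2 gene are argued against by Trac, at most 0.443 CPM in the 3 control libraries of that cohort where the wild-type DN mean was 63.1 CPM. A counting shift between the flow cells is argued against by Rag2 itself, which in Rag2-intact mutants differed between them by 0.1 as the mean of log2 CPM over 3 stages (-0.09, 0.3 and 0.08 in DN, DP and CD8 cells; 0.11, 0.31 and 0.86 from the edgeR fold changes). Another null allele that keeps most of the transcript may explain the 5.75 and remains open, since no count per exon is at hand.

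Genes called between STAT5B-mutant and wild-type cells could come from the flow cells, which follow the groups. Over those genes the cohorts labelled Rag2-/- differed in the same direction by a median of 0.09 in DN, 0.06 in DP and 0.07 in CD8 cells, against median effects of 2.28, 3.6 and 1.34, which argues against a shift as the whole cause; that measure comes from DN cells with that label, and 58.2, 56.6 and 60.8% of the genes shared the sign. Subtracting it left 2, 13 and 258 calls: the fold changes of Ccr2 in CD8 cells were 7.47 ± 1.1 before and 7.19 ± 1.3 after, while Usp18 in CD8 cells, no longer called, went from 1.33 ± 0.44 to 1.94 ± 0.62, as the largest unadjusted p still called fell from 0.00906 to 0.000706 while its own was 0.00487 before and 0.0035 after. Over the 621, 133 and 3055 calls that ended, the median fold change went from 2.27, 3.53 and 1.28 to 1.91, 3.16 and 1.17 and the median SE from 0.56, 0.81 and 0.36 to 0.75, 1.07 and 0.5. B-lineage cells in DN replicate 65, whose Thy1.2 gate would remove them, remain open: over genes called higher in DN cells the other mutant libraries lay 1.04 above wild type against 2.12 in that library, which held 8390 CPM of Igkc, 5080 of Cd74 and 473 of Cd79a.

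Genes of chromosomes 8 and 15 were higher in DP and CD8 libraries of STAT5B mutants labelled Rag2-/-. A shift between flow cells is argued against by the Rag2-intact STAT5B-mutant libraries and the cohort without a mutation there, whose highest median was -0.01 while the lowest of the 6 libraries was 0.33. A programme held by part of the chromosomes is argued against by 8 blocks of neighbouring genes, 4 per chromosome, whose lowest median was 0.3 and highest 0.53. An extra copy of both chromosomes in the sorted cells remains open. The share of genes above 0 (at least 78%, other autosomes at most 55.2%) restates the high medians and cannot test it. DNA was not analysed here.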

How the results depend on the processing

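The fit without STAT5B-mutant DN replicate 65 and DN replicate 93 of the STAT5B mutants labelled Rag2-/- and the mouse as a block in the differences between steps were chosen only after the result was seen; the other alternatives were set down beforehand. Unless said, the cause of a difference was not tested. Of the 29 counts of called genes, RLE factors left all 29 within 1.5 times, no filter 25, the fit without the 2 libraries 21, DESeq2 14 and the compared groups alone 6.

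Without a filter on low counts the first Rag2-null cohort against wild type gave 160 calls instead of 413, STAT5B-mutant DN cells 278 instead of 622 and CD8 cells 2178 instead of 3302, and Stat5a S710F in Rag2-null DN cells 86 instead of 135. All 4 were lower.

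With DESeq2 the moved counts were all higher. The first Rag2-null cohort against wild type gave 1110 and the cohorts against each other 76. Stat5a-mutant cells gave 275 in DN, 50 in DP and 850 in CD8 cells, and STAT5B-mutant cells 1497 in DN and 451 in DP cells. Stat5a S710F in Rag2-null DN cells gave 567, and CD8 against DP gave 1932 in Rag2-null Stat5a mutants and 74 in STAT5B mutants labelled Rag2-/-. The differences gave 26 and 43 for Stat5a, 27 and 42 for STAT5B, and 56 between mutations.

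With the compared groups alone the counts moved both ways. Higher were the first Rag2-null cohort against wild type (4665), the cohorts against each other (64), Stat5a-mutant DP (36) and CD8 cells (3422), STAT5B-mutant DP cells (402), and Stat5a S710F in Rag2-null DN cells (401). Between stages, DP against DN was higher in wild type (9147) and Stat5a mutants (7912), CD8 against DP likewise (7136 and 8229), and the differences gave 745 for Stat5a and 2 and 4 for STAT5B. Lower were STAT5B-mutant DN cells (1), STAT5B mutants labelled Rag2-/- against Rag2-intact ones in DP (2272) and CD8 cells (3069), Rag2-null Stat5a-mutant CD8 cells (715), and DP against DN in STAT5B mutants (1504) and Rag2-null Stat5a mutants (1404). In edgeR 0 genes were called for STAT5B N642H in DN cells labelled Rag2-/-, DP against DN and CD8 against DP of these mutants, and CD8 against DP in Rag2-null Stat5a mutants, with 2113, 1201, 151 and 866 at an unadjusted p of 0.05.

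With the groups alone and the mouse as a block, where stages share mice, DP against DN gave 9112 in wild type (9147 with no block), 8518 in Stat5a mutants and 2183 in Rag2-null Stat5a mutants, and CD8 against DP gave 7741 and 8823 in the first 2. Differences between steps, fitted likewise with the block within genotypes, gave 2 (DP minus DN) and 2087 (CD8 minus DP) for Stat5a S710F and 246 and 778 for STAT5B N642H, and 19 fold changes of genes eligible for naming came to be called. For STAT5B mutants labelled Rag2-/-, edgeR gave 0 for DP against DN (1574 at an unadjusted p of 0.05; 3067 from all libraries) and 0 for CD8 against DP (1967). Replicate numbers that do not pair mice, tried as a block, gave 0 in edgeR for Stat5a S710F in Rag2-null DN cells and for Rag2-null against intact Stat5a-mutant DP and CD8 cells (2581, 3199 and 2193 at an unadjusted p of 0.05). Subtracting the cohort difference left 2, 13 and 258 calls in STAT5B-mutant DN, DP and CD8 cells.

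Without the 2 libraries named above the first Rag2-null cohort gave 1037, Stat5a-mutant DN cells 70 and CD8 cells 688, STAT5B-mutant DN cells 1855 and DP cells 247, Stat5a S710F in Rag2-null DN cells 466, CD8 against DP of STAT5B mutants labelled Rag2-/- 3, and the difference between mutations 14. All 8 were higher.

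Leaving out 1 library at a time moved 76 counts and left 128 within 1.5 times. The lowest and highest were 63 and 184 for the first Rag2-null cohort against wild type, 0 and 16 between the cohorts, 0 and 55 for Stat5a-mutant DN cells, 0 and 0 for DP, 71 and 445 for CD8, 10 and 966 for STAT5B-mutant DN, 12 and 669 for DP and 1024 and 3584 for CD8 cells. In DN cells labelled Rag2-/- they were 0 and 364 for Stat5a S710F and 834 and 3603 for STAT5B N642H. For cells labelled Rag2-/- against Rag2-intact ones they were 1539 and 2769 in Stat5a-mutant DP, 1699 and 3777 in CD8, 2246 and 3519 in STAT5B-mutant DP and 3290 and 5315 in CD8 cells. For DP against DN they were 3332 and 4002 in wild type, 2645 and 3374 in Stat5a mutants, 1302 and 2266 in STAT5B mutants, 1855 and 3412 in Rag2-null Stat5a mutants and 1465 and 5910 in STAT5B mutants labelled Rag2-/-. For CD8 against DP they were 1855 and 2296, 3021 and 3992, 2583 and 4182, 147 and 3379, and 0 and 34 in the same order. The differences ranged from 0 to at most 1 for either mutation against wild type and from 0 to 161 between mutations. Each 0 is a count of edgeR; with all libraries 2145 genes had an unadjusted p of 0.05 or less in Stat5a-mutant DN cells and 302 in DP cells, where DESeq2 called 275 and 50.

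Fold changes that reversed are given with the value from all libraries first. In STAT5B-mutant DN cells against wild type, leaving out replicate 65 turned Csf2rb (5.07 to -0.35), Lmo2 (5.37 to -0.69) and Mef2c (4.88 to -0.63), and leaving out both libraries gave -0.34, -0.72 and -0.63; with any other library left out the highest were 6.58, 7.08 and 5.45. In DP against DN cells of STAT5B mutants, Cd74, Cd79a, H2-Ab1 and Pax5 (-3.79, -5, -3.61 and -5.35) became 1.45, 1.74, 1.24 and 1.63 with the block and 1.48, 1.68, 1.11 and 1.56 without replicate 65, where Igll1 went from -3.72 to 0.11. Without both libraries they were 1.43, 1.64, 1.06 and 1.52, and Igll1 0.07; the lowest with 1 library left out were -4.38, -6.11, -4.2 and -6.95, and -4.31 for Igll1. The B-cell marker median of the STAT5B minus wild-type difference, -3.46, was 1.38 without replicate 65, 1.42 without both and -5.96 without wild-type DN replicate 5, so these values rest on that library.

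In DP against DN cells of STAT5B mutants labelled Rag2-/-, leaving out DN replicate 93, alone or with the other library, turned mt-Co1 (-2.8 to 0.19), mt-Cytb (-2.85 to 0.43), mt-Nd4 (-3.05 to 0.15) and Hes5 (-5.46 to 2.85), and the block turned mt-Co1 to 0.27 and mt-Cytb to 0.43; the lowest values with 1 library left out were -3.29, -3.35, -3.56 and -8.27. Adgre1 went from 4.61 to -0.1 without DP replicate 129 (highest 5.19) and S1pr1 from -4.3 to 1.14 without DN replicate 94 (lowest -5.65). In DN cells of these mutants against controls, Egr3 (3.49 to -0.75) and Zbtb16 (3.36 to -1.7) turned without replicate 94, with highest values of 4.03 and 3.91 without replicate 104. In Rag2-null against intact Stat5a mutants, Maf in DP cells went from 3.5 to -1.63 without replicate 3 (4.08 without replicate 6), and in CD8 cells Il1rl1 from 4.15 to -3.47 without replicate 1, and Arhgef10l (6.28 to -2.42) and Notch1 (1.62 to -0.3) without replicate 6; their highest with 1 library left out were 6.41, 6.91 and 2.16. Cd8b1 for Stat5a S710F in Rag2-null DN cells went from 3.75 to -0.18 without replicate 6, 4.3 without replicate 4 and -0.25 with the block of replicate numbers. Nr4a1 in STAT5B-mutant CD8 cells went from -2.83 ± 0.84 to 1.84 ± 1.13 when the cohort difference was subtracted.

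Of list medians, mitotic genes in STAT5B-mutant DN cells went from -0.3 to 0 without both libraries. For Stat5a S710F in Rag2-null DN cells, glycolysis went from 0.5 to -0.05 with the block, and stroma markers from 0.86 to -0.26 with the groups alone and -0.41 with the block. Among the fold changes of genes eligible for naming, the others were weaker in 1726 values with 1 library left out, stronger in 5 and within bounds in 5916. They were weaker in 311 and stronger in 30 with the groups alone, weaker in 254 with the block, 120 without a filter, 99 with the cohort difference subtracted, 45 without both libraries, 15 with RLE factors and 1 with DESeq2, which made 27 stronger. List medians moved 30 times with 1 library left out, 7 without both libraries, 2 with the groups alone and 1 each with the block and the subtraction.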

Other observations

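What follows was looked at only after the result was seen.

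Thymocytes that carry STAT5B N642H and the Rag2-/- label showed raised expression across 2 whole chromosomes. In their 6 DP and CD8 libraries the chromosome 8 median of 464 genes lay between 0.38 and 0.56 (log2, relative to wild type of the same stage) and the chromosome 15 median of 346 genes between 0.33 and 0.48, while Rag2-intact mutants and cohorts labelled Rag2-/- without a mutation lay from -0.12 to 0 and from -0.17 to 0.14. Over the 6 libraries 81.7% of chromosome 8 genes and 78% of chromosome 15 genes were above 0, against at most 55.2% on any other autosome. Chromosome 7 went the other way there (medians from -0.35 to -0.16; -0.15 to 0.05 in the Rag2-intact mutants and cohorts labelled Rag2-/- without a mutation). Among DN libraries replicate 104 showed the shift as well (0.41 and 0.43), while replicates 93 (0.05 and -0.01) and 94 (-0.04 and -0.04) did not, although the DP and CD8 cells of mouse 94 did. That cells with an extra copy of both grew out in these mice may be a hypothesis for later work. It was not tested.

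Stat5a-mutant Rag2-null cells showed shifts that differed between mice. Chromosome 15 was raised in CD8 replicates 1, 2 and 6 (0.56, 0.43 and 0.34), DP replicates 3 and 6 (0.52 and 0.4) and DN replicate 6 (0.32), and not in DP replicate 4 (0.06) or DN replicates 3 and 4 (0.09 and -0.01). Chromosome 13 was lower in CD8 replicates 1 and 2 (-0.55 and -0.8), and chromosome 4 was higher in CD8 replicate 2 (0.51) and DP replicate 3 (0.28). In CD8 replicate 1 chromosomes 16 and X were also lower (-0.4 and -0.46). Such shifts, in cells with few Trac reads (20.1 ± 13 CPM in DP cells, 400 in wild type), were not tested in DNA.

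Sex-linked transcripts differed between groups: wild-type mice expressed Xist and no Y-linked genes, while the mutant groups mixed the sexes, so sex was not matched. In 2 DN libraries, second-cohort replicate 90 and STAT5B-mutant replicate 65, of which only the latter has a name with a pair of mouse numbers, Xist and Y-linked transcripts were seen together (1190 and 413 CPM of Xist, 49.8 and 80.3 of Ddx3y). In Rag2-null Stat5a-mutant CD8 replicate 1 neither was high (10.3 CPM of Xist, 0 of Ddx3y), and in the STAT5B-mutant CD8 cells of mouse 129, labelled Rag2-/-, Ddx3y was at 107 CPM while Eif2s3y was at 1.01, where replicate 104 had 112 and 97.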
